A study of Culex quinquefasciatus with 7 samples.

How the data were processed

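Messenger RNA of whole adult female Culex quinquefasciatus, the southern house mosquito, was sequenced at 7 times after eclosion, the emergence of the adult from the pupa: 2, 12, 24, 36, 48, 60 and 72 h. Per the labels' protocols, each library was made from a pool of 200 females kept under 12 h of light and 12 h of dark, RNA was extracted with hot acid phenol and treated with DNase, and read pairs of 51 nucleotides with a mean insert of 200 nucleotides were sequenced on an Illumina HiSeq instrument. There is 1 library per time, so no time has a replicate.

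The authors' processing gave 1 value per gene and library, and these values were read as FPKM, fragments per kilobase of gene model, scaled to the mapped fragments of the library. Per the file headers, the deposited table names only the gene and the hour. The unit FPKM was inferred from the TopHat, Cufflinks and Cuffdiff pipeline that the series' design text names and from the values, which are not whole and differ in their sum between libraries. The submitters' processing notes also list CASAVA 1.8 and Trimmomatic. The genome build, the annotation, the use of strand, the handling of reads shared between similar genes and any scaling between libraries are not given in the sources used here. The table held 20305 genes, each under an identifier that starts with CPIJ. The file does not pair identifiers with names, and 0 of the 20305 identifiers matched the 18458 genes of the reference table used. No gene is therefore named, no position is given, and the 34 gene lists fixed in advance by words in gene names (cuticle, salivary proteins, odorant-binding proteins, cytochrome P450s, proteases, ribosomal proteins, clock genes, sperm genes as markers of material from males, and others) could not be built. The planned list results, list alternatives and clock gene values were not run for that reason, and material other than female tissue was not assessed.

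Depth was examined from the low values. Among values above 0 and below 0.3 FPKM, the commonest ratio between a pair of libraries held 12.2% to 25.3% of the genes within 0.02 on the log2 scale, against 1% for ratios spread evenly. Such steps arise when whole fragments are counted, and the commonest ratio is the relative worth of 1 fragment. The 21 pairs of libraries were fitted by 1 depth per library with a largest residual of 0.0029 (log2). Relative to the 2 h library, the depths were 0.928 at 12 h, 1.02 at 24 h, 0.798 at 36 h, 0.831 at 48 h, 0.742 at 60 h and 1.19 at 72 h. These ratios include any scaling the authors applied between libraries. The absolute number of fragments is unknown, so no counting interval was computed and no count test was run.

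All computations used log2(FPKM + 1), a scale that understates the change of genes with low values. Between 2 libraries no test was made: a gene was counted as changed when log2(FPKM + 1) differed by at least 1 (2-fold), among genes with at least 5 FPKM at either time. Over the whole series, limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-dependent prior) tested the slope on time among genes with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 5 residual degrees of freedom of that fit hold both noise and departures from a straight line. A second limma fit on the 6 libraries from 12 to 72 h, with time as a covariate, compared the libraries at 12, 36 and 60 h with those at 24, 48 and 72 h. These lie in opposite phases of the light-dark cycle if all pools emerged at the same hour of the day. This second fit has 3 residual degrees of freedom. Values with 1 number per library were related to time by Pearson's r and Spearman's rho with exact two-sided permutation over all 5040 orders. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 did the rest.

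The fits were tested on simulated data made from the real means and residual spreads of 11837 genes, 200 of them changed. For the slope over 7 libraries, 87 of 100 genes with a slope of 1 per 24 h and 50 of 100 with a slope of 0.5 were recovered, with 11 false calls. For the phase over 6 libraries, 85 of 100 genes with a log2 difference of 2 and 46 of 100 with a difference of 1 were recovered, with 5 false calls. The simulated noise was independent between genes and libraries, without shifts shared by many genes of a library. The false calls are therefore not an error rate for the real data.

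Before the data were examined, the groups, tests, alternatives and the rule for genes given individually were fixed: the largest changes in each direction among genes with at least 10 FPKM at either time (for slopes, called genes with a mean of at least 10 FPKM), of which, without names, at most 2 per direction and comparison are given by identifier. The alternatives were a pseudocount of 0.1, rescaling of the libraries by the median ratio over the 2761 genes with at least 10 FPKM in every library, other minimum values, log2 of time, and each library left out in turn. The relations of library values with time, the 4-fold and 10-fold counts, timing classes, times of the highest value, genes high only in the middle of the series, genes moving one way in every interval, the ranking of abundant genes and the fate of genes after 12 h were added after the data were examined.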

Results

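Gene expression was measured in whole females of Culex quinquefasciatus, a mosquito that takes blood to make its eggs, from 2 to 72 h after emergence of the adult. The series held 7 libraries, 1 each at 2, 12, 24, 36, 48, 60 and 72 h after eclosion, each from 200 pooled females. Values are FPKM, which scale with a transcript's share of the library and not with its amount per animal. With 1 library per time there is no replicate error for any single time, so differences between 2 times are given by size alone and tests run over the whole series.

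The number of genes expressed at 10 FPKM or more rose from 3436 at 2 h to 4021 at 12 h, 4634 at 24 h, 4844 at 36 h and 5352 at 48 h, stood at 5089 at 60 h and reached 5567 at 72 h. It correlated with time over the 7 libraries (Pearson r = 0.941, exact permutation p = 0.0020; Spearman rho = 0.964, exact permutation p = 0.0028), and r was 0.892 without the 2 h and 72 h libraries. The number at 1 FPKM or more went from 10576 to 11920 (r = 0.862, exact permutation p = 0.0026; rho = 0.964, exact permutation p = 0.0028; r = 0.869 without the 2 h and 72 h libraries). Of the 5 relations with time that were computed, these 2 had Benjamini-Hochberg adjusted exact permutation p of 0.0064 for r and 0.0069 for rho. The 10 most abundant genes held 16.7% of all FPKM at 2 h, 12.3% at 12 h, 9.17% at 24 h and 7.63% at 36 h, then 7.85%, 8.52% and 9.26% at 48, 60 and 72 h, a relation with time that did not pass the test (r = -0.73, exact permutation p = 0.055, adjusted 0.068; rho = -0.50, exact permutation p = 0.27, adjusted 0.33; r = -0.74 without the 2 h and 72 h libraries). The sum of FPKM went from 431475 at 2 h to 496974 at 72 h (r = 0.853, exact permutation p = 0.023, adjusted 0.038; rho = 0.821, exact permutation p = 0.034, adjusted 0.057; r = 0.706 without the 2 h and 72 h libraries). The number of genes making up 50% of the sum was 123 at 2 h and 165 at 72 h and did not follow time (r = 0.171, exact permutation p = 0.71, adjusted 0.71; rho = 0.036, exact permutation p = 0.96, adjusted 0.96; r = -0.46 without the 2 h and 72 h libraries).

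The deposited values also shifted as a whole. The median ratio over genes with at least 10 FPKM in every library put the 2 h library at 0.771 and the 72 h library at 1.15 of their geometric mean, a shift of 0.57 on the log2 scale between 2 and 72 h, of 0.25 between 2 and 12 h and of 0.24 between 12 and 24 h. Splits into higher and lower genes are therefore given with the deposited values and again after rescaling by this ratio. After rescaling, 4181 genes reached 10 FPKM at 2 h and 5007 at 72 h, and the count still correlated with time (r = 0.948, exact permutation p = 0.00079).

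The profiles separated along time. Across 11837 genes with a mean of at least 1 FPKM, which are not independent replicates, the correlation of log2(FPKM + 1) between neighbouring libraries was 0.916 from 2 to 12 h, 0.937 from 12 to 24 h and 0.972 from 24 to 36 h, and between 0.979 and 0.983 from then on. The 2 h and 72 h libraries correlated at 0.745. The first principal component held 77.5% of the variance and ran from the 2 h to the 72 h library, with the 48 h and 60 h libraries close together. The second held 11.4% and set the 12 h and 24 h libraries apart from both ends of the series. Both components used the deposited values without rescaling, so they include the shift of whole libraries.

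**Figure D1:**
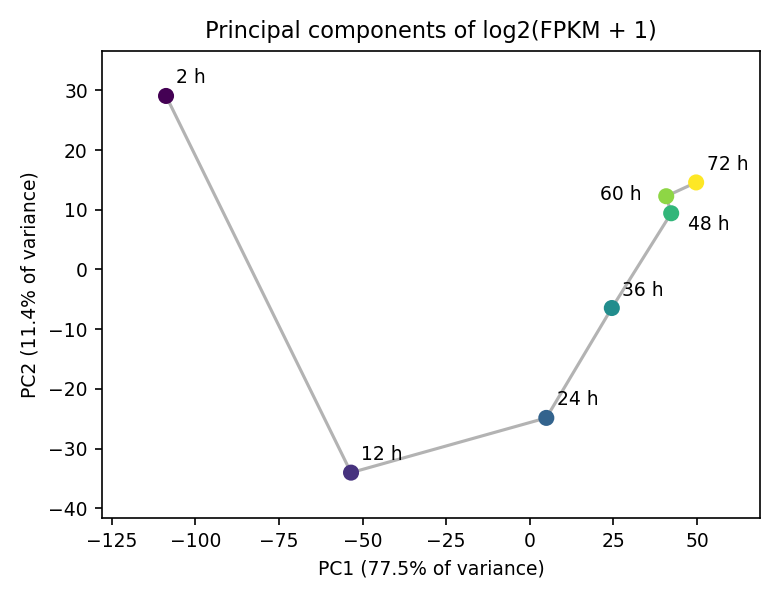
Principal components 1 (x axis, 77.5% of the variance) and 2 (y axis, 11.4%) of log2(FPKM + 1), unitless scores, with 1 point per library joined in order of time. The deposited values were used without rescaling. The largest steps lie between 2, 12 and 24 h, and the libraries at 48, 60 and 72 h lie close together.

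The first hours after eclosion were compared through the libraries at 2 h and 12 h. Of 6764 genes with at least 5 FPKM at either time, 756 were at least 2-fold higher and 421 at least 2-fold lower at 12 h. After rescaling the split was 549 higher and 647 lower, so which direction held more genes depended on the scaling. At least 4-fold differences were seen in 217 genes that were higher and 124 that were lower (179 and 171 after rescaling), and at least 10-fold differences in 71 and 40 (66 and 52). The largest increases were in CPIJ010337, from 1.41 to 496 FPKM (log2 change 7.69), and CPIJ010338, from 1.88 to 261 FPKM (6.51). Both had lower values afterwards: CPIJ010337 stood at 196 FPKM at 24 h and 109 FPKM at 72 h, and CPIJ010338 at 23.2 and 10.3 FPKM. The largest decreases were in CPIJ017620, from 1078 to 4.28 FPKM (log2 change -7.67), and CPIJ008211, from 124 to 0.360 FPKM (-6.53). Both stayed low, at 0.783 and 0.283 FPKM at 72 h.

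Among genes with at least 20 FPKM at 2 h or 12 h, 368 were at least 2-fold higher at 12 h. At 72 h, 246 of these were within 2-fold of their 12 h value, 63 were at least 2-fold above it and 59 at least 2-fold below it. After rescaling these counts were 191, 32 and 71 of 294 genes. Of the 271 genes that were at least 2-fold lower at 12 h, 162 were within 2-fold of that value at 72 h, 91 were at least 2-fold below it and 18 at least 2-fold above it (264, 147 and 16 of 427 genes after rescaling). The 12 h library enters both steps, so an error in it moves a gene in opposite directions in the 2 steps.

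**Figure D2:**
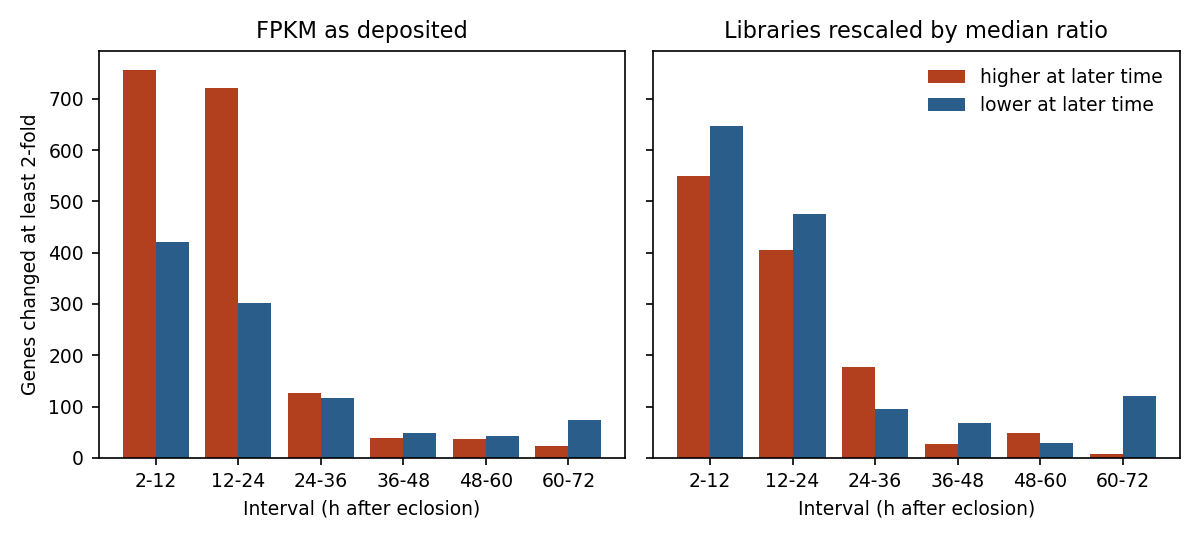
Number of genes (y axis) at least 2-fold higher or lower at the later time of each interval (x axis, hours after eclosion), among genes with at least 5 FPKM at either time, with the deposited values on the left and after rescaling on the right. Counts are near 1000 in the intervals that end at 12 h and 24 h (1177 and 1024 with the deposited values) and at most 272 in the later ones under either scaling, while the balance of higher and lower genes depends on the scaling.

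The later intervals were compared in the same way. From 12 to 24 h, 722 genes were at least 2-fold higher and 302 at least 2-fold lower (406 and 476 after rescaling), of 7578 genes. The largest increase was in CPIJ005273, from 35.3 to 3613 FPKM (log2 change 6.64), and the largest decrease in CPIJ013785, from 298 to 1.02 FPKM (-7.21). From 24 to 36 h the counts fell to 127 higher and 116 lower (177 and 95 after rescaling), and 24 genes were at least 4-fold lower against 0 at least 4-fold higher, under either scaling. The largest decrease of this interval was in CPIJ003470, from 1149 to 15.1 FPKM (-6.16), one of the most abundant genes at 12 h with 5648 FPKM. From 36 h on, few genes differed between neighbouring libraries: 39 higher and 49 lower from 36 to 48 h (27 and 67 after rescaling), 37 and 42 from 48 to 60 h (48 and 29), and 24 and 73 from 60 to 72 h (7 and 121). The median absolute log2 difference, over the genes with at least 5 FPKM at either time of the interval, was 0.44 from 2 to 12 h and 0.45 from 12 to 24 h, against 0.25, 0.24, 0.18 and 0.28 in the later 4 intervals. These values include the shift of whole libraries. After rescaling they were 0.35 and 0.38, against 0.25, 0.19, 0.16 and 0.22.

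Some of the late extremes were single libraries. The gene with the largest increase from 48 to 60 h also had the largest decrease from 60 to 72 h: it was listed at 0 at 48 h, between values of 17.5 FPKM at 36 h and 19.5 FPKM at 60 h, and stood at 1.03 FPKM at 72 h. The gene with the largest decrease from 36 to 48 h went from 19.0 to 0.0738 FPKM and back to 17.6 FPKM at 60 h. A listed 0 in such a table can be a failed estimate.

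The start and the end of the series were compared through the libraries at 2 h and 72 h. Of 8678 genes with at least 5 FPKM at either time, 4138 were at least 2-fold higher at 72 h and 818 at least 2-fold lower (2244 and 1357 after rescaling). At least 4-fold differences were seen in 1092 genes that were higher and 338 that were lower, and after rescaling in 519 and 549. At least 10-fold differences were seen in 176 and 148 (126 and 202 after rescaling). At 4-fold and 10-fold, which direction held more genes thus depended on the scaling. The largest increases were in CPIJ005273, from 1.34 to 1643 FPKM (log2 change 9.45), and CPIJ007471, from 1.35 to 1617 FPKM (9.43). CPIJ005273 was already at its maximum at 24 h with 3613 FPKM, while CPIJ007471 was higher in every successive library. The largest decreases were in CPIJ003588, from 11145 to 8.86 FPKM (-10.14), and CPIJ017875, from 3509 to 4.45 FPKM (-9.33). CPIJ003588 was at 3628 FPKM at 12 h and 163 FPKM at 24 h, and CPIJ017875 was at 5697 FPKM at 12 h before its decline. Among the genes counted as higher, 9 were listed at 0 at 2 h, and among those counted as lower, 8 were listed at 0 at 72 h.

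**Figure D3:**
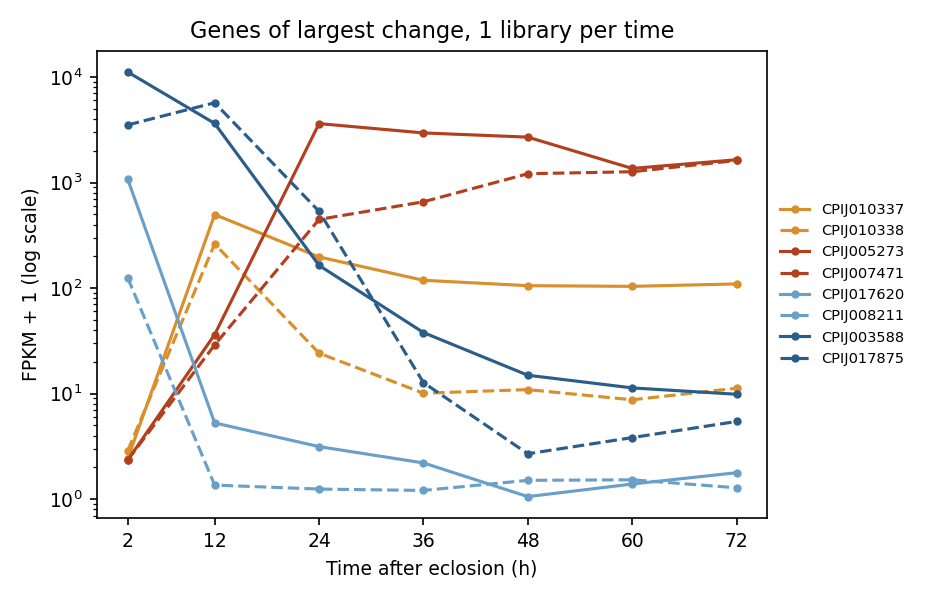
FPKM + 1 (y axis, log scale) against hours after eclosion (x axis) for the 8 genes with the largest increases and decreases from 2 to 12 h and from 2 to 72 h, 1 point per library. CPIJ010337 and CPIJ010338 are highest at 12 h, CPIJ005273 and CPIJ007471 pass 400 FPKM by 24 h, and CPIJ017620 and CPIJ008211 have dropped by 12 h. CPIJ003588 declines from 2 h on, and CPIJ017875 declines between 12 h and 48 h.

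The genes with large differences between 2 and 72 h had made most of their change by 24 h. Among the 1092 genes at least 4-fold higher at 72 h than at 2 h, 27.9% had passed 50% of their log2 change by 12 h and 86.0% by 24 h. The median part of the change reached was 26.0% at 12 h, 67.4% at 24 h, 76.2% at 36 h and 90.9% at 48 h. The 338 genes at least 4-fold lower had covered a median of 40.1% at 12 h, 80.1% at 24 h and 95.6% at 36 h, and 87.3% of them had passed 50% by 24 h. After rescaling, the percentages past that point by 24 h were 81.1% of 519 higher genes and 88.2% of 549 lower genes.

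**Figure D4:**
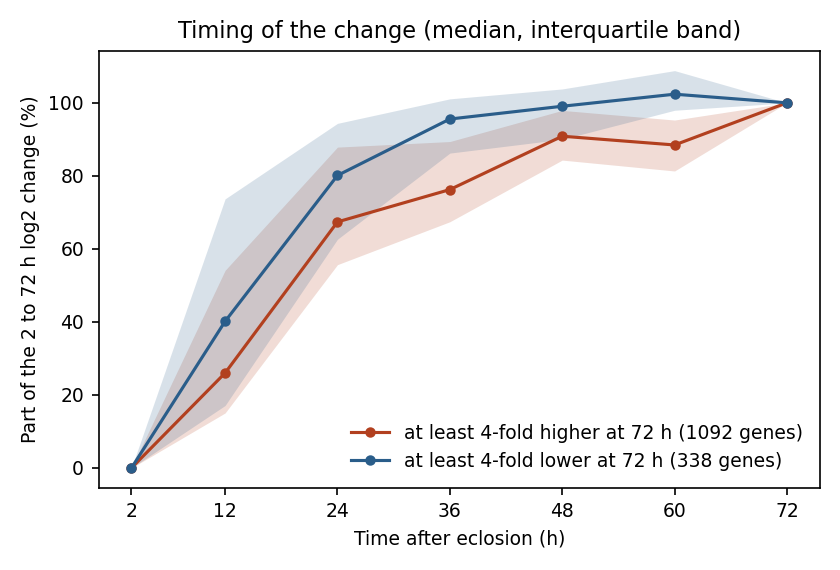
Part of the log2 change from 2 to 72 h that was reached at each time (y axis, %) against hours after eclosion (x axis), as the median (line) and interquartile range (band) over 1092 genes at least 4-fold higher and 338 genes at least 4-fold lower at 72 h. By definition the values are 0% at 2 h and 100% at 72 h. The medians pass 50% between 12 h and 24 h in both groups of genes.

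Over the whole series, 6122 of 11837 genes had a slope on time that passed limma's test at a Benjamini-Hochberg adjusted p of 0.05. Of these, 5254 rose, with a median slope of 0.45 per 24 h on the log2 scale (interquartile range 0.34 to 0.60, median standard error 0.095), and 868 fell, with a median slope of -0.53 (interquartile range -0.83 to -0.38, median standard error 0.12). A slope of at least 1 per 24 h in size was found in 192 rising and 156 falling genes (116 and 193 after rescaling). After rescaling, 3749 genes rose and 1220 fell. Without the 2 h library 3968 genes were called, 3335 of them rising, and 3745 of the 6122 genes kept their call and direction. Among all genes tested, 601 were higher in every successive library and 36 were lower in every one (493 and 112 after rescaling), where independent noise gives 2.35 in each direction. All genes share the same 7 libraries, so counts far from 2.35 can arise by chance, and these counts were not tested.

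The steepest rising slopes were those of CPIJ007471, 2.92 ± 0.56 per 24 h (standard error, 7 libraries, limma adjusted p = 0.0040), and CPIJ005273, 2.75 ± 0.92 (limma adjusted p = 0.035). Without the 2 h library the slope of CPIJ005273 was 1.32 (limma adjusted p = 0.22). Its call was also lost, with slopes between 2.55 and 2.99, after rescaling, with no minimum value, and without the 12 h, the 48 h or the 60 h library. The steepest falling slopes were those of CPIJ017875, -4.13 ± 0.66 (limma adjusted p = 0.0022), and CPIJ003470, -4.09 ± 0.64 (limma adjusted p = 0.0021). Each of these 2 kept its call without any single library.

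The gene with the highest FPKM was not the same through the series. CPIJ012572 was the most abundant at 2 h, with 12982 FPKM, and fell to 129 FPKM at 24 h and 21.4 FPKM at 72 h (slope -3.32 ± 0.60 per 24 h, limma adjusted p = 0.0033). CPIJ008101 was the most abundant at 12 h and 24 h, with 7722 and 6954 FPKM, and stood at 1974 FPKM at 72 h. CPIJ009303 rose from 1392 FPKM at 2 h to 7157 FPKM at 72 h and was the most abundant at every time from 36 h on (slope 0.79 ± 0.14, limma adjusted p = 0.0034). These 3 genes were chosen after their values were seen. Of the 100 most abundant genes at 2 h, 81 were among the 100 most abundant at 12 h, 56 at 24 h and 37 at 72 h. Of 158 genes that reached 1000 FPKM in any library, 16 did so in all 7.

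The light-dark cycle under which the mosquitoes were kept places successive 12 h samples in opposite phases, if all pools emerged at the same hour of the day. With time as a covariate, 0 of 11837 genes differed between the libraries at 12, 36 and 60 h and those at 24, 48 and 72 h at a limma adjusted p of 0.05. At an unadjusted limma p under 0.05, 1075 genes differed, of which 324 were higher at 12, 36 and 60 h and 751 lower. After rescaling 873 genes differed, 670 higher and 203 lower. Evenly spread p-values would give 592, but other splits of these 6 libraries gave between 93 and 2288 such genes. The number 592 is therefore not a chance level for these data. The count was 194 without the 60 h library, 291 without the 24 h library and 562 without time as a covariate. It was between 1089 and 1316 without any one of the other 4 libraries. Fits with 1 library left out have fewer residual degrees of freedom. The hour of lights-on relative to the sampling is not given in the sources used here. In simulated data of this design, 46 of 100 genes with a log2 difference of 1 and 85 of 100 with a difference of 2 were recovered. That simulation placed the whole difference between the 2 sampled phases, with noise independent between genes. Samples 12 h apart cover only 2 phases of the cycle, so a rhythm with equal values at both would be missed at any size. The result of 0 genes thus does not exclude daily rhythms.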

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

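Leaving out each library in turn gave between 3968 (without the 2 h library) and 6587 (without the 24 h library) genes with a linear trend against 6122, and 0 genes with a phase difference each time. The trend count was 2360 of 4859 genes with a mean of at least 10 FPKM, fewer because fewer genes were tested. It was 3352 with a phase term and without the 2 h library, a fit with fewer libraries and residual degrees of freedom. Among single libraries left out, the 2 h library weighed most. The trend count was 3968 without it alone and 5071 to 6587 without any 1 other library. It stayed within 1.5 times with a pseudocount of 0.1 (6080), rescaling (4969), no minimum (6313) and log2 of time (7685). Without a minimum, 18283 genes were tested against 11837, and 5469 of the 6122 genes kept their call. Those of the 6122 that could be tested again (at least 6067 under each of these 4 settings and each library omission) never took the opposite sign. This was largely set in advance: the genes were chosen for their slopes in the same libraries, and dropping the minimum leaves a slope unchanged. With at least 20 FPKM required, fewer genes could enter and the 2-fold counts were 639 of 2542 from 2 to 12 h, 502 from 12 to 24 h, 121 from 24 to 36 h, 32 from 36 to 48 h, 32 from 48 to 60 h, 48 from 60 to 72 h and 2105 from 2 to 72 h. With no minimum, 138 genes were counted from 36 to 48 h and 134 from 48 to 60 h, and with a pseudocount of 0.1, 148 from 60 to 72 h, because lower values then enter or weigh more. The other 2-fold counts stayed within 1.5 times, but rescaling moved the part that was higher from 64.2% to 45.9% (2 to 12 h), 70.5% to 46.03% (12 to 24 h), 52.3% to 65.1% (24 to 36 h), 44.3% to 28.7% (36 to 48 h), 46.8% to 62.3% (48 to 60 h), 24.7% to 5.47% (60 to 72 h), 83.5% to 62.3% (2 to 72 h) and 85.8% to 75.4% (trend). Of 36 alternative log2 changes of single genes between 2 times, 9 moved by over 1.5-fold and 0 changed sign, and of 52 alternative slopes 7 lost their call, all of CPIJ005273. Depth limits the low values: the 60 h library is the shallowest, at 0.742 of the 2 h library. No paired analysis was possible because each time has a single library. The results for gene lists and their other settings were not run, since no list could be built.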

Other observations

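Of the tests in this part, the one of time courses 2 identifiers apart was chosen after the result was seen, as were the counts of genes high only in the middle of the series and the runs of successive identifiers.

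A set of genes was high only in the middle of the series. Relative to both the 2 h and the 72 h library, 228 genes with a mean of at least 1 FPKM were at least 2-fold higher at 1 or more of the 5 times between, and 51 were at least 2-fold lower (239 and 53 after rescaling). At least 5 FPKM was also required at the time between, at 2 h or at 72 h. Of the 228, 64 were at their highest at 12 h, 92 at 24 h, 30 at 36 h, 17 at 48 h and 25 at 60 h. In 73 genes the excess was seen in at least 2 successive libraries, and in 6 genes the deficit was. Among 7465 genes with at least a 2-fold range, the highest value fell at 2, 12, 24, 36, 48, 60 and 72 h in 947, 464, 613, 270, 993, 923 and 3255 genes, and the lowest in 5385, 598, 253, 129, 195, 595 and 310. After rescaling, 6046 genes had such a range, with the highest value in 1571, 532, 381, 286, 577, 1095 and 1604 genes and the lowest in 3004, 799, 516, 144, 325, 626 and 632, so that the 2 h and 72 h libraries held similar numbers of highest values.

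Genes with neighbouring identifiers had similar time courses. The mean correlation of time courses was 0.411 for genes 1 number apart, above the highest of 1000 shuffles (0.269), and 0.333 at 2 numbers apart (highest shuffle 0.264). At 5 numbers apart it was 0.264, which 2 of 1000 shuffles reached. Of 217 genes at least 4-fold higher at 12 h than at 2 h, 65 lay in 25 runs of successive identifiers, the longest of 9, with 40 successive pairs against a mean of 2.79 and a highest of 9 in shuffles. The 2 largest increases, CPIJ010337 and CPIJ010338, are such a pair. Of the 124 genes at least 4-fold lower at 12 h, the 121 that entered this count made 12 successive pairs (shuffled mean 0.895, highest 5). Those at least 4-fold higher at 72 h made 187 (71.4, 97). Of the 338 at least 4-fold lower at 72 h, 333 entered and made 52 (6.67, 16).

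If identifiers were numbered along the genome, which the file does not state, clusters of duplicated or co-regulated genes may account for this, as a hypothesis that no test here sets apart from the alternatives. Single genes split into 2 models with successive identifiers cannot be the whole cause, since the excess at 2 numbers apart (0.333) was also above all shuffles, although the bound written first, at 5 numbers apart, was not passed. Reads shared between similar neighbouring genes, and genes split into more than 2 models, stay open, since no sequence was used here.

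More genes changed before 24 h than after. The lower of the first 2 interval counts was 4.21 times the highest later count, 3.24 times after rescaling and 3.18 times among genes with at least 100 FPKM, so neither library scaling nor counting noise in weakly expressed genes accounts for it by itself. Age after eclosion remains the design's own explanation and cannot be separated from differences between single pools, since each time has 1 library.

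With the deposited values, more genes were at least 2-fold higher than lower at 72 h than at 2 h (83.5% of those changed). Rescaling by the median ratio left 62.3% at 2-fold and none of the imbalance at 4-fold (519 higher, 549 lower), so library scaling stays open as a cause, although centring on that median partly fixes this outcome. With the 316 genes that were among the 200 most abundant of any library removed and the rest set to equal sums, 67.7% of the changed genes were still higher at 72 h, and 65.2%, 68.3% and 67.4% were at 36, 48 and 60 h. The removed genes held 63.8% of the FPKM at 2 h and 56.3% at 72 h, so reads taken by them may account for part of the imbalance. The median log2 change of the remaining genes tested, from 2 to 72 h, was still 0.48. Equal sums thus did not centre these genes, and the test cannot decide whether abundant genes account for the rest. Against the shallowest library, at 60 h, 79.2% of changed genes were higher, which argues against the greater depth at 72 h as the cause. The 2 h library is a single pool that enters every one of these values.

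For the trend, 1 of 100 orders of the 7 times, the real one, gave as many called genes (6122, highest other order 4759, median 0). The other orders were drawn without the real one and its exact reverse, whose calls were not computed. A chance order can thus be excluded at that level only among the orders drawn. Only the deposited values were reordered, so a shift of whole libraries along time could also place the real order first. For the phase, 3 of the 10 splits of the 6 libraries, the real one included, gave at least the 1075 genes of the real one at an unadjusted p under 0.05. The highest other was 2288, for 12, 60 and 72 h against the rest, a split that also called 56 genes after adjustment against 0 for the real one, and 10 splits are too few for a share under 0.05. After rescaling the real split gave 873 such genes (highest other 1889), which cannot decide on library scaling, because the real split did not stand out before rescaling either.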
